A study of Mus musculus with 55 samples.

How the data were processed

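RNA was measured by sequencing in 55 libraries from 3 hindlimb muscles of mice: the flexor digitorum brevis (FDB), a small foot muscle, the extensor digitorum longus (EDL), a fast lower-leg muscle, and the soleus (SOL), a slow and oxidative one. The mice were wild type or mdx, a strain that lacks full-length dystrophin because of a mutation in Dmd and is the standard mouse model of Duchenne muscular dystrophy, and were 2 or 5 months old. Muscle, genotype and age make 12 groups, and each library was assigned to its group from the submitters' sample labels. Per the labels' protocols, muscles were kept in an RNase-blocking preservative, RNA was extracted with Trizol, polyadenylated RNA was isolated with a NEBNext module, and libraries were made with a NuGEN kit on a Mondrian SP workstation. The labels do not say that replicates are separate animals, so p-values measure the spread between these libraries, which may in part be technical, and the labels tie no libraries to one animal across muscles.

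The authors deposited RPKM (reads per kilobase of transcript, scaled to the library's mapped reads in mega-reads, M) for 24453 genes. Per the file headers, reads were mapped to mm10 with TopHat and RPKM were computed in Partek. The submitters' processing notes name CASAVA 1.8.2, TopHat2 2.1.0 and Partek 6.6. The gene annotation, the use of strand and the handling of reads that map to several places are not given in the sources used here, so genes with close copies and overlapping genes are uncertain. The authors' second deposited table holds, per the file headers, a q-value from an ANOVA in Partek and a ratio of mdx to wild type for each gene in each of the 6 muscle and age comparisons. At 2 months the deposited ratio equals that of geometric means of RPKM + 0.1 (24453 genes, within 0.01 log2). At 5 months it does so in all 24453 genes only when the 2 ID blocks of the mdx libraries are weighted equally, and in 42.2% to 55.3% of genes when libraries are pooled. Beyond this check, that table was used only for a side-by-side count of genes.

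Depth was read from the RPKM values, since the value of 1 read in a short gene depends only on the library's total and the gene's length. Steps between low values of 3261 genes spanning under 1500 bases gave 20.3 to 66.8 M reads per library, with a median of 50.4 M. Between 73.3% and 85.0% of such low values lay within 0.1 read of a whole number, so the recovery is approximate and no count test was run. No 2 of the 55 libraries held identical values, and Pearson's r across genes within the 108 pairs of one group was 0.973 to 0.9978. Library numbers fall into 3 blocks, ns01 to ns48, ns49 to ns53 and ns54 to ns65, and the last 2 hold mdx libraries at 5 months only. The sources give no date or run, so the block is used as a possible batch, and values within blocks are given beside many of the 5-month results.

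Values were analysed as log2(RPKM + 1), which understates the change of low genes, for the 12541 genes with a mean of at least 0.5 RPKM over the libraries. One limma model with 12 group means was fitted (lmFit, eBayes with trend), so that small groups borrow the spread of the others. Contrasts were mdx minus wt in each muscle at each age, the difference of these effects between ages (genotype by age) and between muscles (an F test and 3 pairwise contrasts per age), and 5 minus 2 months within each genotype. P-values were adjusted by the Benjamini-Hochberg method over genes within a contrast, with a threshold of 0.05, and "rose" and "fell" are used of genes past it. Gene lists with at least 5 measured members, 35 of the 38 written, were tested with camera at its preset inter-gene correlation of 0.01, adjusted over the lists and contrasts of a family. The test was repeated with an estimated correlation, and fry tested each list against no change. Member counts are given over all genes tested and adjusted over the list alone, and list medians are given less the median of all genes. The model, the lists, the alternatives and the rule for naming genes were fixed before the data were examined.

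The rule names Dmd first in every group, then in each mdx comparison the 5 largest rises and 5 largest falls among genes past the threshold with at least 1 RPKM in a group. It adds 2 to 4 passing members of each list described, and the 10 largest and 10 smallest medians among genes past the threshold with one sign in all 6 comparisons. It also takes the 5 largest values of each sign for each interaction and age contrast, the 10 smallest p of each F test, and Myh1, Myh2, Myh4, Myh7, Tubb6 and Utrn. Genes with RIKEN, Gm or LOC names may be left unnamed. Some genes that the rule takes are not reported here, although they stay in every test and count of genes and lists.

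Simulated data had 200 of 12541 genes changed per comparison. For mdx minus wt the model recovered 82.1% to 94%, 97% to 100% and 100% of genes changed 1.5-, 2- and 4-fold. It called 5 to 12 unchanged genes. For genotype by age the shares were 70.1% to 77.6%, 91% to 97% and 100%, with 7 to 10 such calls. For genotype by muscle they were 73.1% to 86.6%, 97% to 98.5% and 98.5% to 100%, with 8 to 9. For age within a genotype they were 85.1% to 97%, 92.5% to 98.5% and 100%, with 6 to 10. Camera called all 9 planted lists of 20 genes and 0 of 270 others, but a median of 58 of 210 in relabelled real data.

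Alternatives fixed beforehand were a pseudocount of 0.1, no filter or a mean of at least 5 RPKM, median-of-ratios scaling, quantile normalization, robust eBayes, array weights, only the compared groups, draws of 3 libraries per group and each library left out in turn. Leaving out the second or the third ID block, weighting ID blocks equally and removing each library's trend with transcript length were added after the data were seen. Gene positions are from GENCODE M21 on mm10 (GRCm38), which gave one position for 24030 genes (98.3%). Computation used R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The mitochondrial genome, B cell and T cell lists had no measured member and were not tested. No comparison with human patients was made.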

Results

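Gene expression was measured by RNA sequencing in 55 libraries of FDB, EDL and SOL muscle from mdx and wild-type mice. The FDB groups held 3 mdx and 4 wild-type libraries at 2 months of age and 7 and 4 at 5 months. For EDL the numbers were 4 and 4 at 2 months and 6 and 4 at 5 months, and for SOL 4 and 4, then 7 and 4. Depth recovered from the RPKM values was 43.6 to 66.3 M reads per FDB library, 20.3 to 62.0 M per EDL library and 21.3 to 66.8 M per SOL library. The shallowest SOL libraries were the 4 mdx ones of the second ID block at 5 months, with 21.3 to 25.8 M reads, against 44.7 to 60.5 M for the 3 of the third block. The series was designed to compare the degree and time course of mdx pathology between muscles, so mdx was set against wild type in each muscle at each age, and the effects were then compared between ages and between muscles.

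Dmd, the dystrophin gene (ENSMUSG00000045103.17, chromosome X, 82948870 to 85206141, mm10), carries the mdx mutation and was lower in every mdx group. Its wild-type level was 11.7 ± 0.252 RPKM in FDB (SD, n = 4), 7.52 ± 0.296 in EDL (n = 4) and 9.24 ± 0.58 in SOL (n = 4) at 2 months, and 11.5 ± 0.618, 6.94 ± 0.386 and 9.27 ± 0.111 at 5 months (n = 4 each). In mdx libraries it was 3.71 ± 0.238 in FDB (n = 3), 1.89 ± 0.0757 in EDL (n = 4) and 2.80 ± 0.138 in SOL (n = 4) at 2 months. At 5 months the mdx level was 3.46 ± 0.171 in FDB (n = 7), 1.98 ± 0.107 in EDL (n = 6) and 2.31 ± 0.581 in SOL (n = 7). On the log2(RPKM + 1) scale Dmd fell by 1.43, 1.56 and 1.43 in FDB, EDL and SOL at 2 months (adjusted p = 9.31e-18, 6.23e-21 and 2.31e-19) and by 1.48, 1.41 and 1.65 at 5 months (adjusted p = 3.18e-22, 3.29e-21 and 6.47e-24). Every mdx library lay below every wild-type library of its muscle and age. Within ID blocks at 5 months the Dmd change was −1.51 and −1.46 in the first and the third block of FDB, −1.37 and −1.43 in EDL, and −1.83 and −1.42 in the second and the third block of SOL. The change did not differ detectably between ages (genotype by age adjusted p = 0.858, 0.443 and 0.137 for FDB, EDL and SOL).

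Utrn encodes utrophin, the autosomal relative of dystrophin (chromosome 10, 12382188 to 12869365). It rose in FDB at 5 months, from 4.65 ± 0.504 (n = 4) to 8.07 ± 2.05 RPKM (n = 7), by 0.65 log2 (adjusted p = 2.54e-06, higher in 7 of 7 libraries). Within ID blocks the rise was 0.30 in the first and 0.92 in the third. The Utrn differences in FDB at 2 months (0.31, adjusted p = 0.0719), EDL (0.13 and 0.10, adjusted p = 0.427 and 0.449) and SOL (0.16 and −0.19, adjusted p = 0.316 and 0.126) did not pass. For EDL at 5 months the Utrn sign turned to −0.24 with quantile normalization, and in SOL at 5 months it was −0.43 in the second block and 0.12 in the third. Tubb6, a beta-tubulin, rose in all 6 comparisons, by 0.89 and 0.93 log2 in FDB, 1.95 and 1.38 in EDL and 1.19 and 1.31 in SOL at 2 and 5 months (adjusted p = 0.00249, 2.53e-05, 3.05e-10, 2.41e-08, 1.22e-05 and 4.66e-08). In each, all Tubb6 values in mdx exceeded those in wild type.

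**Figure D1:**
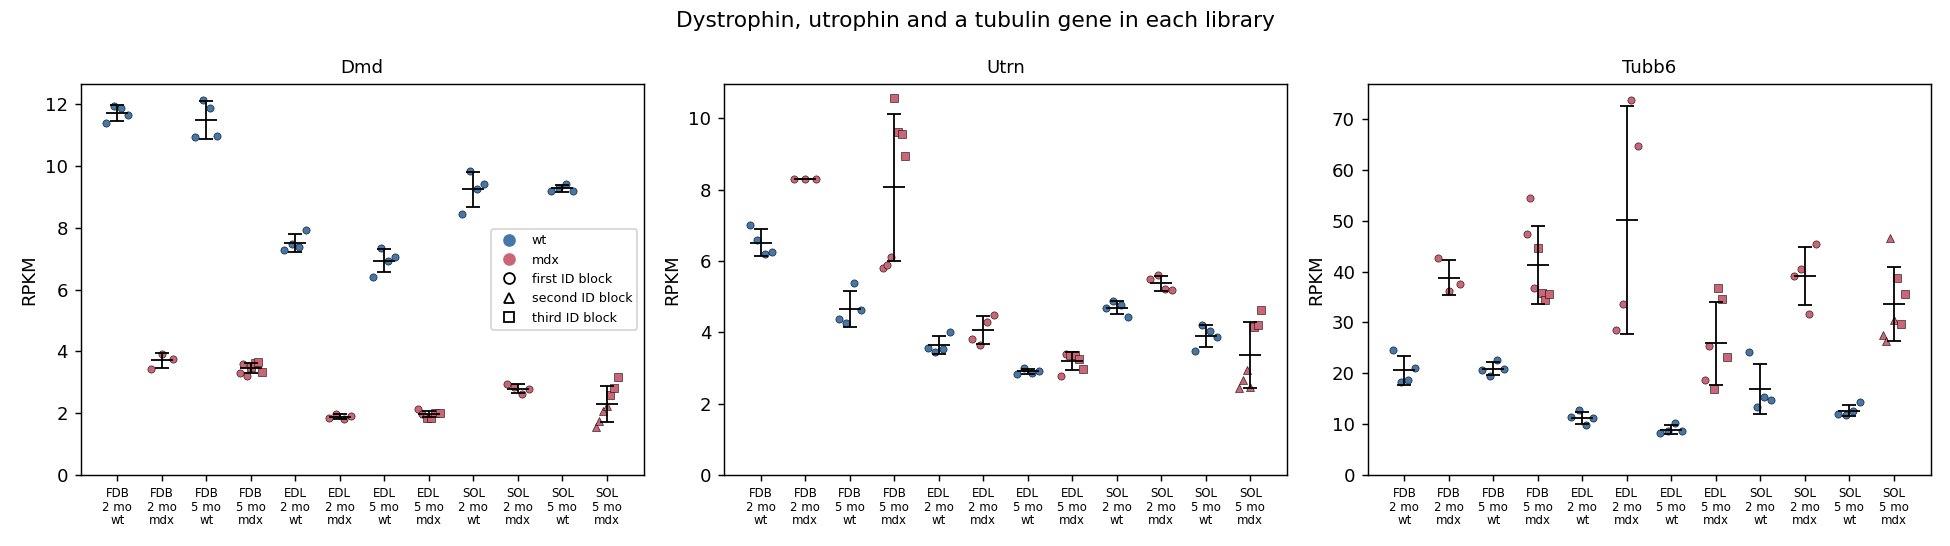
RPKM of Dmd, Utrn and Tubb6 in each library by muscle, age and genotype (blue wild type, red mdx; circles, triangles and squares for the first, the second and the third ID block), with bars at the mean ± SD. Dmd was lower and Tubb6 higher in each mdx library than in the wild-type libraries of its group, while Utrn passed the test only in FDB at 5 months.

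The adult myosin heavy chains mark fibre types. Myh4 (type IIB) was at 9427 ± 409 RPKM in wild-type EDL at 2 months (n = 4), against 572 ± 55.8 in FDB (n = 4) and 386 ± 85.7 in SOL (n = 4). Myh7 (type I) was at 1751 ± 86.3 in SOL, 254 ± 17.9 in FDB and 1.8 ± 0.645 in EDL. Myh2 (type IIA) fell in EDL by 1.09 and 0.86 log2 at 2 and 5 months (adjusted p = 0.000194 and 0.000709) and in SOL at 5 months by 0.79 (adjusted p = 0.00129), where it was lower in 7 of 7 libraries. Its fall in FDB at 5 months, by 0.51 (adjusted p = 0.034), was −0.05 with quantile normalization, and the other two Myh2 differences, −0.36 in FDB and −0.31 in SOL at 2 months, did not pass (adjusted p = 0.284 and 0.327). Myh4 fell in SOL at 2 months (−2.43, adjusted p = 0.0083, lower in 4 of 4 libraries). Myh7 rose in EDL at 2 months by 1.15 (adjusted p = 0.0179) and Myh1 (type IIX) in SOL at 5 months by 0.46 (adjusted p = 0.0406), and both calls were lost under other settings.

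In FDB at 2 months the largest rises in mdx were in genes of new muscle fibres. Tmem8c, which encodes myomaker, a membrane protein needed for myoblast fusion, rose from 0.601 ± 0.14 RPKM (n = 4) to 14.4 ± 5.03 (n = 3), by 3.21 log2 (SE 0.491, adjusted p = 1.18e-05). Myl4, an embryonic myosin light chain, rose from 11.6 ± 0.817 to 57.9 ± 14.1 RPKM, the perinatal myosin Myh8 from 5.85 ± 0.824 to 30.9 ± 9.02, and the embryonic myosin Myh3 from 8.95 ± 0.78 to 41.9 ± 9.33 (2.19, 2.19 and 2.09 log2, adjusted p = 0.00016, 0.000209 and 0.00159). Actc1, the cardiac actin also used in developing muscle, rose by 2.05 (adjusted p = 0.000712). The largest falls besides Dmd were in Etohi1, from 3.24 ± 0.189 to 0.365 ± 0.135 RPKM (−1.64, adjusted p = 0.000302), and in 3 Gm genes, Gm14325, Gm14295 and Gm14326 (−2.10, −1.96 and −1.90), all on chromosome 2. These 4 genes have close copies there, so their reads are uncertain. For all 10 of these genes the 3 mdx libraries lay beyond the 4 wild-type libraries, which chance gives for 5.71% of unselected genes, while these were chosen as the largest changes.

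By list, 14 of the 17 regeneration genes rose in FDB at 2 months (14 adjusted over the list alone), with a median of 1.46 log2 relative to all genes. Regeneration genes as a list had camera adjusted p = 2.82e-05, and adjusted p = 0.572 with an estimated correlation. Macrophage genes rose in 23 of 24 cases (24 adjusted over the list alone), with the protease Ctss at 1.64, the lectin Lgals3 at 1.53 and the receptor Trem2 at 1.43. The macrophage list had adjusted p = 3.46e-05, and adjusted p = 0.744 with an estimated correlation. Of 12 complement genes 10 rose (12 adjusted over the list alone), with C4b at 1.29 and C7 at 1.13, and 12 of 14 markers of fibroadipogenic progenitors rose (13 adjusted over the list alone), with Pi16 at 1.06. These lists, in this order, had adjusted p = 0.000538 and 0.000561, and adjusted p = 0.616 for both with an estimated correlation. Antigen presentation genes rose in 10 of 12 cases (10 adjusted over the list alone), with Cd74 at 1.38 and H2-Ab1 at 1.37. Extracellular matrix genes rose in 17 of 29 (19 adjusted over the list alone), with Timp1 at 1.40 and Fn1 at 1.16. Their adjusted p was 0.00344 and 0.00455, and adjusted p = 0.744 and 0.799 with an estimated correlation. All 7 erythroid genes rose, with the globins Hbb-bs at 1.45 and Hbb-b1 at 1.43 (7 adjusted over the list alone). The erythroid list had adjusted p = 0.0293, and adjusted p = 0.744 with an estimated correlation.

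Lists of energy metabolism lay lower than other genes in FDB at 2 months, although many members did not pass. Of the 75 nuclear genes of the respiratory chain 20 fell and 55 did not pass (17 fell adjusted over the list alone), with Cox6a2 at −0.42 and Atp5g1 at −0.37. Of 17 genes of the tricarboxylic acid cycle 12 fell (15 adjusted over the list alone), with Idh3b and Idh3g both at −0.35. Of 18 glycolysis and glycogen genes 11 fell (14 adjusted over the list alone, with 1 higher), with Phkg1 at −0.59, Gpd1 at −0.57 and Pygm, muscle glycogen phosphorylase, at −0.50. Of 22 fatty acid oxidation genes 11 fell (11 adjusted over the list alone, with 1 higher), with Etfb at −0.39 and lipoprotein lipase Lpl at −0.37. The 4 lists had adjusted p = 5.21e-24, 8.06e-17, 3.66e-12 and 2.78e-10, and adjusted p = 0.516, 0.314, 0.259 and 0.516 with an estimated correlation. The fast fibre list lay lower than other genes, at a median of −0.36 relative to all genes, with 0 of 14 members past the threshold and a sign that turned to 0.03 with quantile normalization. The fast fibre list had adjusted p = 0.000674, and adjusted p = 0.516 with an estimated correlation. The calcium handling list was lower by its test and its median (−0.02, −0.15 relative to all genes), although its mean was 0.01, with Sln, an inhibitor of the calcium pump, at 1.18 and Jph1 at −0.30 among 2 members that rose and 3 that fell of 18 (2 and 3 adjusted over the list alone, adjusted p = 0.00851). The circadian list was lower by its test, yet its only passing members, Npas2 (0.60) and Clock (0.29), rose among 16 (1 adjusted over the list alone, adjusted p = 0.015). With an estimated correlation both lists had adjusted p = 0.516.

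Of 12541 genes tested, 4338 passed in FDB at 2 months, 3761 higher and 577 lower in mdx, and 90 rose and 9 fell at least 2-fold. The median of all genes was itself higher by 0.125, so the direction of small changes depends on the scaling. With median-of-ratios scaling 3170 genes passed, 1398 higher and 1772 lower. The share higher was 86.7% as deposited, 44.1% so scaled, 43.2% with quantile normalization and 43.3% with the length trend removed. Like scaling, that step removed the all-gene shift (median −0.02), so its shares do not test length. Without library ns01 the count was 2616.

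In FDB at 5 months genes of immune cells, fat and myoblast fusion were among the largest rises. H2-Aa, a class II antigen-presenting chain, rose from 5.59 ± 1.37 (n = 4) to 44.8 ± 16.4 RPKM (n = 7), by 2.75 log2 (adjusted p = 4.93e-11). The rise was 3.14 in the first ID block and 2.45 in the third. Cfd, adipsin, which fat cells secrete, rose from 5.99 ± 3.85 to 49.2 ± 29.5 RPKM (2.73, adjusted p = 6.6e-06), with 1.64 and 3.54 in the blocks. Tmem8c rose again, from 0.228 ± 0.0858 to 10.5 ± 7.77 RPKM (2.97, adjusted p = 2.21e-08, blocks 3.90 and 2.28). Mir6240 and Mrgpra6 had the largest values (3.72 and 3.63, adjusted p = 0.00819 and 0.00271), but these came from the third block alone (6.66 and 6.36) and not the first (−0.19 and −0.01). Among falls, Erdr1, which has no position in GENCODE M21, dropped from 22.4 ± 4.87 to 0.0832 ± 0.111 RPKM (−4.41, adjusted p = 1.04e-08, blocks −4.42 and −4.41). In 8 of the 10 genes with the largest changes the 7 mdx libraries lay beyond the 4 wild-type libraries (0.606% of unselected genes by chance), Mir6240 and Mrgpra6 being the exceptions.

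All 24 macrophage genes rose in FDB at 5 months (24 adjusted over the list alone), with Ctss at 2.38 and lysozyme Lyz2 at 2.32 and medians relative to all genes of 1.58 in the first block and 1.39 in the third. The macrophage list had adjusted p = 1.99e-05, and adjusted p = 0.744 with an estimated correlation. All 12 complement genes rose, with C4b at 2.08 and C3 at 2.03, as did all 12 antigen presentation genes (12 each adjusted over the list alone). The complement and antigen presentation lists had adjusted p = 1.86e-05 and 7.58e-05, and adjusted p = 0.516 and 0.565 with an estimated correlation. Extracellular matrix genes rose in 28 of 29 cases (28 adjusted over the list alone), with fibronectin Fn1 at 1.81 and Timp1 at 1.73, and the block medians were 0.91 and 0.89. The matrix list had adjusted p = 5.97e-05, and adjusted p = 0.744 with an estimated correlation. All 14 fibroadipogenic markers rose, with Pi16 at 2.14, as did all 11 chemokines and cytokines, with Ccl8 at 2.43 (14 and 11 adjusted over the lists alone). The fibroadipogenic and chemokine lists had adjusted p = 0.000142 and 0.0293, and adjusted p = 0.565 and 0.744 with an estimated correlation. The regeneration list did not pass camera although 15 of 17 members rose, with medians of 1.87 in the first block and 0.82 in the third. Also short of its threshold, 10 of 11 Schwann cell genes and 8 of 10 adipocyte genes rose, and both moved with the ID block. The Schwann cell median relative to all genes was −0.15 in the first block (1 of 11 rose) and 0.88 in the third (11 rose), and the adipocyte median was 0.39 and 0.89.

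All 17 tricarboxylic acid cycle genes fell in FDB at 5 months (17 adjusted over the list alone), with Idh3a at −0.44. Of 75 respiratory chain genes 39 fell (38 adjusted over the list alone), with Cox7a1 at −0.51 and Ndufb5 at −0.43. Their adjusted p was 3.66e-12 and 1.56e-20, and adjusted p = 0.314 and 0.525 with an estimated correlation. The respiratory chain fall was larger in the third block (69 fell, median −0.52) than in the first (33 fell, median −0.24), the same block in which Schwann cell and fat genes were higher. Fatty acid oxidation genes fell in 13 of 22 cases and 1 rose (13 and 1 adjusted over the list alone), with Acot13 at −0.38. Glycolysis genes fell in 14 of 18 cases and 2 rose (14 and 2 adjusted over the list alone), with Pgm1 at 0.57, Phkg1 at −0.50 and Pygm at −0.48. For these the adjusted p was 2.9e-08 and 3.19e-08, and adjusted p = 0.516 and 0.314 with an estimated correlation. The fast fibre list had 2 members that rose and 5 that fell of 14 (2 and 5 adjusted over the list alone), with Mybpc2 at 0.82 and Tnnt3 at −0.53, and its median of −0.46 relative to all genes turned to 0.03 with quantile normalization. As a list, fast fibre genes had adjusted p = 0.000605, and adjusted p = 0.516 with an estimated correlation. Calcium handling and atrophy genes were lower by their tests while their medians were 0.05 and 0.04 before the all-gene shift was taken off (−0.13 and −0.14 after, the first 0.00 with quantile normalization). The passing members went both ways, 5 up and 6 down of 18 (5 and 6 adjusted over the list alone) with Sln at 1.77 and Trdn at −0.80, and 4 up and 2 down of 16 (2 and 2 adjusted over the list alone) with Cdkn1a at 1.73 and Fbxo32 at −0.49. For these lists the adjusted p was 0.00579 and 0.0491, and adjusted p = 0.516 for both with an estimated correlation.

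In total 7847 genes passed in FDB at 5 months, 6660 higher and 1187 lower, with 571 and 24 changed at least 2-fold, and the all-gene median was 0.178. Median-of-ratios scaling gave 7810 genes, 3547 higher and 4263 lower, a share higher of 45.4% against 84.9% as deposited, and quantile normalization and length correction gave 39.2% and 43.0%. Against wild type alone, the first-block libraries gave 6870 genes and the third-block libraries 8560, and the mdx libraries of the 2 blocks differed in 3720 genes.

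**Figure D2:**
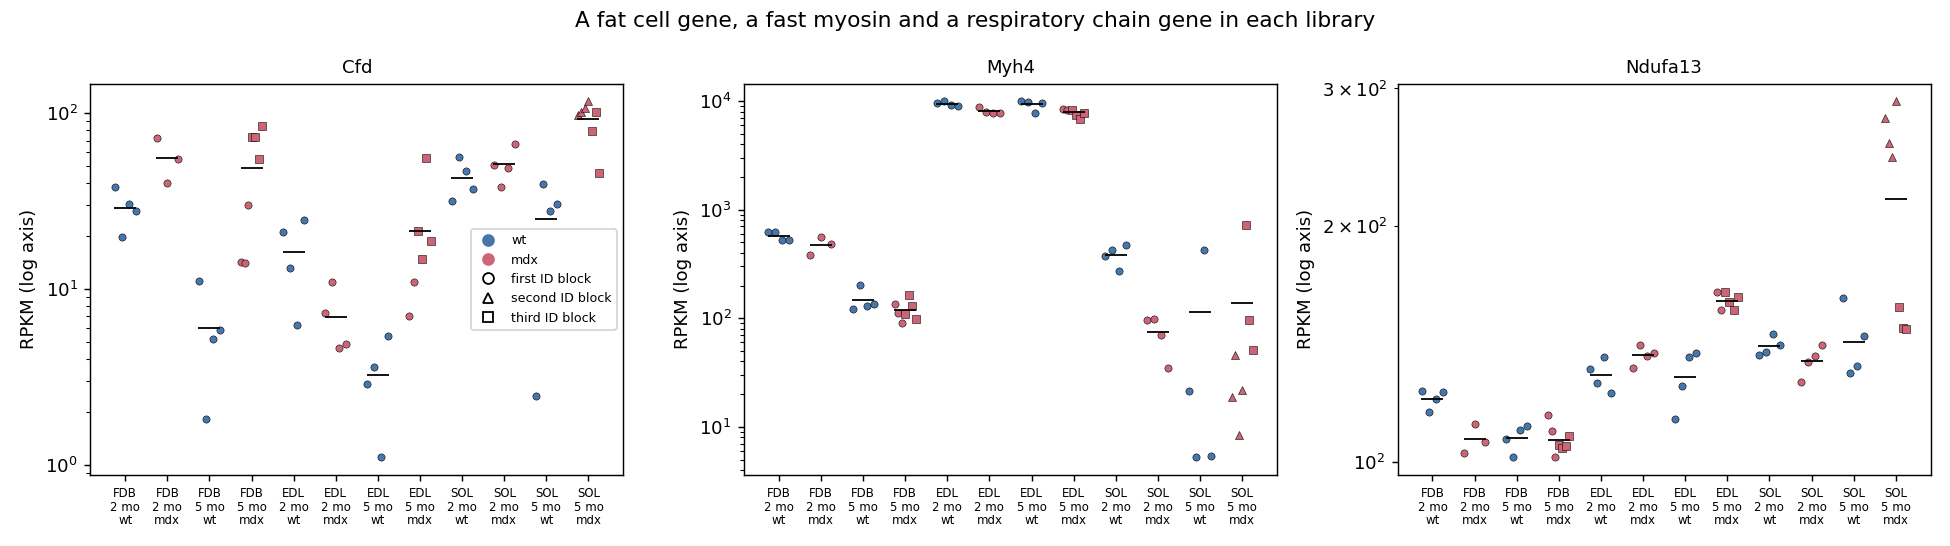
RPKM of Cfd, Myh4 and Ndufa13 in each library on a log axis by muscle, age and genotype (blue wild type, red mdx; circles, triangles and squares for the first, the second and the third ID block), with a bar at each mean. Cfd averaged 71.5 RPKM in third-block and 19.5 RPKM in first-block mdx FDB libraries at 5 months.

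In EDL at 2 months the mdx libraries had more RNA of developing and slow muscle and of a stress-induced metallothionein. Myh3 rose from 1.72 ± 0.205 (n = 4) to 47.4 ± 38.0 RPKM (n = 4), by 3.69 log2 (adjusted p = 1.3e-08), and Tnni1, the slow troponin I, from 2.33 ± 0.0877 to 40.6 ± 23.4 (3.42, adjusted p = 2.86e-10). Mt2, a metal-binding stress protein, rose from 5.31 ± 2.1 to 152 ± 153 RPKM (4.16, adjusted p = 2.9e-06). Falls were led by Erdr1 (21 ± 4.44 to 1.53 ± 2.9, −3.66, adjusted p = 8.75e-06). Ppp1r1a, an inhibitor of protein phosphatase 1, fell from 26.7 ± 3.17 to 3.46 ± 0.736 RPKM (−2.64, adjusted p = 1.07e-20). Dusp26, a dual-specificity phosphatase, fell from 35.9 ± 2.14 to 7.42 ± 1.28 (−2.14, adjusted p = 9.7e-17). For all 10 genes with the largest changes the 4 mdx libraries lay beyond the 4 wild-type ones (2.86% of unselected genes by chance).

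All 24 macrophage genes rose in EDL at 2 months (24 adjusted over the list alone), with Lgals3 at 3.28 and Ctss at 2.93. Of 17 regeneration genes 16 rose (16 adjusted over the list alone), with the growth factor Igf2 at 3.11 and Myl4 at 2.87. Their adjusted p was 1.35e-09 and 2.24e-06, and adjusted p = 0.522 and 0.516 with an estimated correlation. All 16 interferon response genes rose, with Irf7 at 1.62 and Oasl2 at 1.57, as did all 12 antigen presentation genes, with H2-Aa at 2.17 (16 and 12 adjusted over the lists alone). The interferon and antigen presentation lists had adjusted p = 0.000533 and 0.000179, and adjusted p = 0.744 and 0.616 with an estimated correlation. All 11 cell cycle genes rose, with Rrm2 at 1.25 and Top2a at 1.19, and 10 of 11 chemokines, with Spp1, osteopontin, at 2.72 (11 and 11 adjusted over the lists alone). The cell cycle and chemokine lists had adjusted p = 0.00228 and 0.00642, and adjusted p = 0.679 and 0.637 with an estimated correlation. Extracellular matrix genes rose in 23 of 29 cases and 1 fell (23 and 1 adjusted over the list alone), with Timp1 at 3.09 and Postn at 2.58. Complement genes rose in 8 of 12 cases (9 adjusted over the list alone), with C3ar1 at 1.91. The matrix and complement lists had adjusted p = 0.00146 and 0.0483, and adjusted p = 0.744 and 0.773 with an estimated correlation. Genes of the synapse and of denervated muscle rose in 10 of 17 cases (11 adjusted over the list alone), with the fetal acetylcholine receptor subunit Chrng at 2.54 and Runx1 at 1.59. Costamere and repair genes rose in 13 of 20 cases and 1 fell (13 and 1 adjusted over the list alone), with annexin Anxa5 at 1.24. These 2 lists had adjusted p = 0.0189 and 0.0293, and adjusted p = 0.522 and 0.744 with an estimated correlation. Slow fibre genes rose in 9 of 12 cases and 1 fell (9 and 1 adjusted over the list alone), with Casq2 at 1.86. The slow fibre list had adjusted p = 0.0491, and adjusted p = 0.744 with an estimated correlation.

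Lower lists in EDL at 2 months included the circadian clock, in which 9 of 16 genes fell and 3 rose (9 and 3 adjusted over the list alone), with the output factors Hlf at −1.90 and Dbp at −1.25 and the period gene Per2 at −1.34. The circadian list had adjusted p = 4.46e-05, and adjusted p = 0.314 with an estimated correlation. Fatty acid oxidation genes fell in 13 of 22 cases and 1 rose (14 and 1 adjusted over the list alone), with Lpl at −0.93. The fatty acid oxidation list had adjusted p = 2.47e-10, and adjusted p = 0.516 with an estimated correlation. Respiratory chain genes fell in 13 of 75 cases (2 adjusted over the list alone), with Cox6a2 at −0.54, and tricarboxylic acid cycle genes in 6 of 17 (6 adjusted over the list alone), with Suclg2 at −0.38. These lists had adjusted p = 2.85e-08 and 2.83e-06, and adjusted p = 0.744 and 0.516 with an estimated correlation. Of 11 Schwann cell genes 4 fell (4 adjusted over the list alone), with Ncmap at −0.68. The Schwann cell list had adjusted p = 0.00261, and adjusted p = 0.744 with an estimated correlation. In all 6307 genes passed, 5217 higher and 1090 lower, with 488 and 45 changed at least 2-fold and an all-gene median of 0.138. With median-of-ratios scaling 5948 passed, 2843 higher and 3105 lower. The share higher was 47.8% against 82.7% as deposited, 40.5% with quantile normalization and 46.6% after length correction.

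By 5 months the largest rises in mdx EDL were in matrix, macrophage and stretch-responsive genes. Ankrd1, a titin-associated protein induced by stretch, rose from 5.09 ± 1.71 (n = 4) to 72.0 ± 33.3 RPKM (n = 6), by 3.51 log2 (adjusted p = 6.34e-12, blocks 3.70 and 3.41). Cilp, a cartilage and tendon matrix protein, rose from 3.89 ± 1.27 to 45.8 ± 5.00 (3.30, adjusted p = 3.36e-16, blocks 3.19 and 3.35). Ctss rose from 2.86 ± 1.11 to 39.6 ± 27.8 (3.19, adjusted p = 3.35e-10, blocks 2.97 and 3.30). Erdr1 fell from 21.8 ± 3.03 to 0.0809 ± 0.0595 RPKM (−4.39, adjusted p = 1.88e-08, blocks −4.38 and −4.40) and Dusp26 from 36.0 ± 4.60 to 3.30 ± 0.885 (−3.12, adjusted p = 1.62e-24, blocks −3.40 and −2.98). All 6 mdx libraries lay beyond the 4 wild-type ones for the 10 genes with the largest changes (0.952% of unselected genes by chance).

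All 29 extracellular matrix genes rose in EDL at 5 months (29 adjusted over the list alone), with Postn, periostin, at 2.55, Timp1 at 2.52 and Col3a1 at 2.50, and with block medians of 1.24 and 1.43. The matrix list had adjusted p = 1.55e-08, and adjusted p = 0.565 with an estimated correlation. All 11 tendon genes rose (11 adjusted over the list alone), with lubricin Prg4 at 2.47, Comp at 2.18 and Thbs4 at 2.16, with a median of 0.96 in the first block and 1.82 in the third. The tendon list had adjusted p = 0.00832, and adjusted p = 0.744 with an estimated correlation. All 24 macrophage genes and all 12 antigen presentation genes rose (24 and 12 adjusted over the lists alone), with Lgals3 at 2.89 and H2-Ab1 at 3.03. The macrophage and antigen presentation lists had adjusted p = 8.6e-06 and 0.000265, and adjusted p = 0.72 and 0.616 with an estimated correlation. Complement genes rose in 11 of 12 cases, with factor B, Cfb, at 2.03, and all 17 regeneration genes rose, with Igf2 at 2.87 and Actc1 at 2.80 (11 and 17 adjusted over the lists alone). The complement and regeneration lists had adjusted p = 0.0203 and 0.0197, and adjusted p = 0.744 for both with an estimated correlation. The regeneration median was 0.76 in the first block and 1.28 in the third. Costamere and repair genes rose in 16 of 20 cases (16 adjusted over the list alone), with Anxa1 at 1.47 and the keratin Krt18 at 1.43. The costamere and repair list had adjusted p = 0.0446, and adjusted p = 0.744 with an estimated correlation. Fatty acid oxidation genes fell in 20 of 22 cases (20 adjusted over the list alone), with Lpl at −1.31 and the fatty acid carrier Fabp3 at −0.77, and with block medians of −0.64 and −0.58. The fatty acid oxidation list had adjusted p = 9.33e-21, and adjusted p = 0.314 with an estimated correlation.

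Respiratory chain genes fell in 12 of 75 cases in EDL at 5 months and 1 rose (3 fell adjusted over the list alone), with Ndufb5 at −0.42. Tricarboxylic acid cycle genes fell in 6 of 17 cases (4 adjusted over the list alone), with Suclg2 at −0.38. These lists had adjusted p = 1.88e-09 and 1.41e-06, and adjusted p = 0.744 and 0.516 with an estimated correlation. The Schwann cell list was lower than other genes (median −0.37 relative to all genes, −0.49 and −0.30 in the blocks). As deposited 2 of its 11 members rose and 1 fell, with Egr2 at 0.68 and Ncmap at −0.46, while 0 rose and 3 fell with median-of-ratios scaling (0 adjusted over the list alone). The Schwann cell list had adjusted p = 0.0159, and adjusted p = 0.744 with an estimated correlation. The count was 8621 genes, 7552 higher and 1069 lower, with 650 and 55 changed at least 2-fold and an all-gene median of 0.229. Median-of-ratios scaling gave 7517, with 3587 higher and 3930 lower, a share higher of 47.7% against 87.6% as deposited, and 41.3% and 47.3% came from quantile normalization and length correction.

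In SOL at 2 months regeneration and immune genes again led the rises. Myh8 rose from 2.12 ± 0.65 (n = 4) to 60.4 ± 33.5 RPKM (n = 4), by 4.15 log2 (adjusted p = 4.12e-11). H2-Aa rose from 9.19 ± 6.49 to 67.5 ± 14.0 (2.91, adjusted p = 1.86e-09). Myh4 fell from 386 ± 85.7 to 74.7 ± 29.5 RPKM (−2.43, adjusted p = 0.0083). Erdr1 fell from 14.8 ± 5.55 to 4.96 ± 5.93 (−2.04, adjusted p = 0.0105), in 3 of 4 libraries, and did not pass with one library left out (−1.45, adjusted p = 0.088). In the other 9 of the 10 genes with the largest changes the 4 mdx libraries lay beyond the 4 wild-type libraries (2.86% of unselected genes by chance).

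Macrophage genes rose in 23 of 24 cases in SOL at 2 months, with Lyz2 at 2.57, and all 12 antigen presentation genes rose (23 and 12 adjusted over the lists alone). The macrophage and antigen presentation lists had adjusted p = 3.78e-13 and 4.12e-07, and adjusted p = 0.516 for both with an estimated correlation. Extracellular matrix genes rose in 23 of 29 cases (23 adjusted over the list alone), with Col3a1 at 1.70, and fibroadipogenic markers in 10 of 14 (11 adjusted over the list alone), with Mfap5 at 1.3. The matrix and fibroadipogenic lists had adjusted p = 5.14e-07 and 0.000485, and adjusted p = 0.616 for both with an estimated correlation. Regeneration genes rose in 16 of 17 cases (17 adjusted over the list alone), with Myh3 at 2.72 and Myl4 at 2.68, and complement genes in 10 of 12 (11 adjusted over the list alone), with C3ar1 at 1.8. The regeneration and complement lists had adjusted p = 1.13e-06 and 2.24e-06, and adjusted p = 0.516 for both with an estimated correlation. Costamere and repair genes rose in 13 of 20 cases, with Anxa1 at 1.23, and all 11 cell cycle genes rose, with Rrm2 at 1.09 (13 and 11 adjusted over the lists alone). The costamere and cell cycle lists had adjusted p = 0.000856 and 0.00306, and adjusted p = 0.525 and 0.709 with an estimated correlation. Chemokines rose in 8 of 11 cases, with Ccl6 at 2.1, and interferon response genes in 12 of 16, with Oas1a at 1.03 (8 and 12 adjusted over the lists alone). The chemokine and interferon lists had adjusted p = 0.00404 and 0.0203, and adjusted p = 0.616 and 0.799 with an estimated correlation.

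Fatty acid oxidation genes fell in 18 of 22 cases in SOL at 2 months (19 adjusted over the list alone), with Lpl at −0.95 and Acadm at −0.51. Circadian genes fell in 8 of 16 cases and 2 rose (9 and 2 adjusted over the list alone), with Hlf at −1.15 and Dbp at −1.09. The fatty acid oxidation and circadian lists had adjusted p = 1.68e-16 and 0.000554, and adjusted p = 0.314 and 0.448 with an estimated correlation. Respiratory chain genes fell in 9 of 75 cases (1 adjusted over the list alone), with Cox6a2 at −0.37, and tricarboxylic acid cycle genes in 8 of 17 (9 adjusted over the list alone), with Suclg2 at −0.40. These lists had adjusted p = 1.03e-08 and 2.69e-07, and adjusted p = 0.744 and 0.516 with an estimated correlation. In the Schwann cell list 1 of 11 genes fell (0 adjusted over the list alone), and in the atrophy list 4 of 16 fell and 2 rose (4 and 2 adjusted over the list alone), with Eda2r at 1.08 and the ubiquitin ligase Fbxo32 at −0.51. These lists had adjusted p = 0.0147 and 0.0359, and adjusted p = 0.744 and 0.516 with an estimated correlation, and the atrophy list's mean was 0.07 where its median was −0.10. In all 5010 genes passed, 4047 higher and 963 lower, with 297 and 26 changed at least 2-fold and an all-gene median of 0.099. Median-of-ratios scaling gave 5148, with 2365 higher and 2783 lower, and the share higher went from 80.8% as deposited to 45.9%, and to 41.3% and 43.8% with quantile normalization and length correction.

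At 5 months the 5 largest rises in mdx SOL were 4 genes of class II antigen presentation and Ccl8. H2-Ab1 rose from 3.15 ± 1.45 (n = 4) to 66.7 ± 17.6 RPKM (n = 7), by 4.05 log2 (adjusted p = 1.01e-16), with 4.28 in the second ID block and 3.76 in the third. H2-Aa rose from 3.50 ± 1.59 to 67.7 ± 19.3 (3.95, adjusted p = 1.54e-15, blocks 4.22 and 3.59). Lrtm1, a leucine-rich repeat membrane protein gene, fell from 10.4 ± 0.587 to 1.17 ± 0.347 RPKM (−2.40, adjusted p = 9.71e-22, blocks −2.52 and −2.24). Erdr1 fell from 17.9 ± 4.64 to 2.88 ± 4.85 (−3.18, adjusted p = 6.78e-06, blocks −2.44 and −4.16). Apoo-ps, a pseudogene, fell by 2.48 in the pooled libraries (adjusted p = 5.18e-05), by 4.27 in the second block and by 0.10 in the third. In the other 9 of the 10 genes with the largest changes the 7 mdx libraries lay beyond the 4 wild-type libraries (0.606% of unselected genes by chance).

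Extracellular matrix genes rose in 27 of 29 cases in SOL at 5 months (29 adjusted over the list alone), with the fibrillar collagens Col3a1 at 2.72 and Col1a1 at 2.33 and block medians of 1.38 and 1.48. The matrix list had adjusted p = 5.33e-10, and adjusted p = 0.516 with an estimated correlation. Macrophage genes rose in 23 of 24 cases (23 adjusted over the list alone), with Ctss at 3.60 and Lgals3 at 3.20 and block medians of 2.05 and 1.53. The macrophage list had adjusted p = 2.77e-08, and adjusted p = 0.565 with an estimated correlation. All 12 antigen presentation and all 12 complement genes rose, with Cfb at 2.15, as did all 14 fibroadipogenic markers, with Pi16 at 2.03 (12, 12 and 14 adjusted over the lists alone). These immune and progenitor lists had adjusted p = 6.25e-06, 1.21e-05 and 2.82e-05, and adjusted p = 0.516 for each with an estimated correlation. All 17 regeneration genes rose, with Myl4 at 3.14 and Myh8 at 2.96, and 10 of 11 chemokines (17 and 10 adjusted over the lists alone). The regeneration and chemokine lists had adjusted p = 0.002 and 0.0189, and adjusted p = 0.744 for both with an estimated correlation. Fatty acid oxidation genes fell in 18 of 22 cases (19 adjusted over the list alone), with Lpl at −1.14 and block medians of −0.46 and −0.62. Tricarboxylic acid cycle genes fell in 8 of 17 cases (8 adjusted over the list alone), with Suclg2 at −0.44. The fatty acid oxidation and tricarboxylic acid cycle lists had adjusted p = 2.24e-16 and 2.82e-05, and adjusted p = 0.314 and 0.565 with an estimated correlation. The endothelial list was lower by its test and its mean (−0.01), while its median was 0.05 (−0.13 relative to all genes). Of 12 members 1 rose, Cldn5 at 0.96, and 3 fell, among them the receptor Flt1 at −0.92 (1 and 2 adjusted over the list alone). The endothelial list had adjusted p = 0.0441, and adjusted p = 0.762 with an estimated correlation. The respiratory chain list did not pass, and its members went with the ID block, with 59 of 75 higher in the second block (median 0.38 relative to all genes) and 39 lower in the third (median −0.32). Pooled, 37 rose and 5 fell as deposited, while 7 rose and 16 fell with median-of-ratios scaling.

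The count in SOL at 5 months was 8055 genes, 6636 higher and 1419 lower, with 607 and 38 changed at least 2-fold and an all-gene median of 0.178. Median-of-ratios scaling gave 7537 genes, 3772 higher and 3765 lower, and the share higher went from 82.4% to 50%, with 39.9% after quantile normalization and 46.9% after length correction. Against wild type the second-block libraries gave 8608 genes and the third-block libraries 7562, and 5359 genes differed between these mdx libraries. No mdx SOL library at 5 months came from the first block, which held all wild-type libraries, so block and genotype cannot be told apart there.

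**Figure D3:**
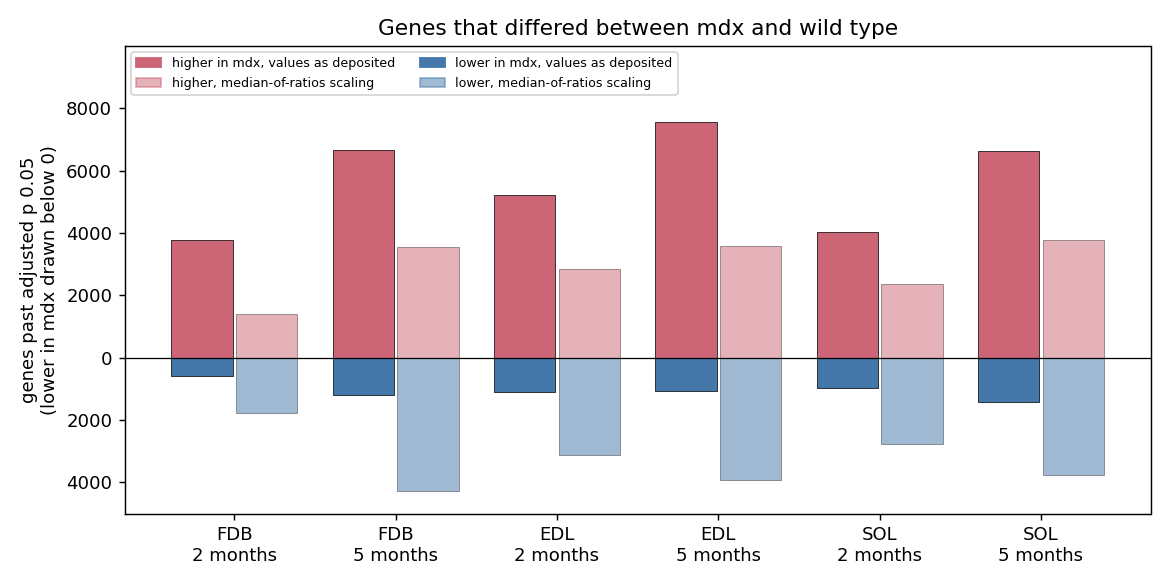
Genes past an adjusted p of 0.05 in the 6 comparisons of mdx with wild type, with genes higher in mdx drawn above 0 and genes lower below 0, as deposited and with median-of-ratios scaling. As deposited 80.8% to 87.6% of the genes were higher, and after scaling 44.1% to 50%.

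**Figure D4:**
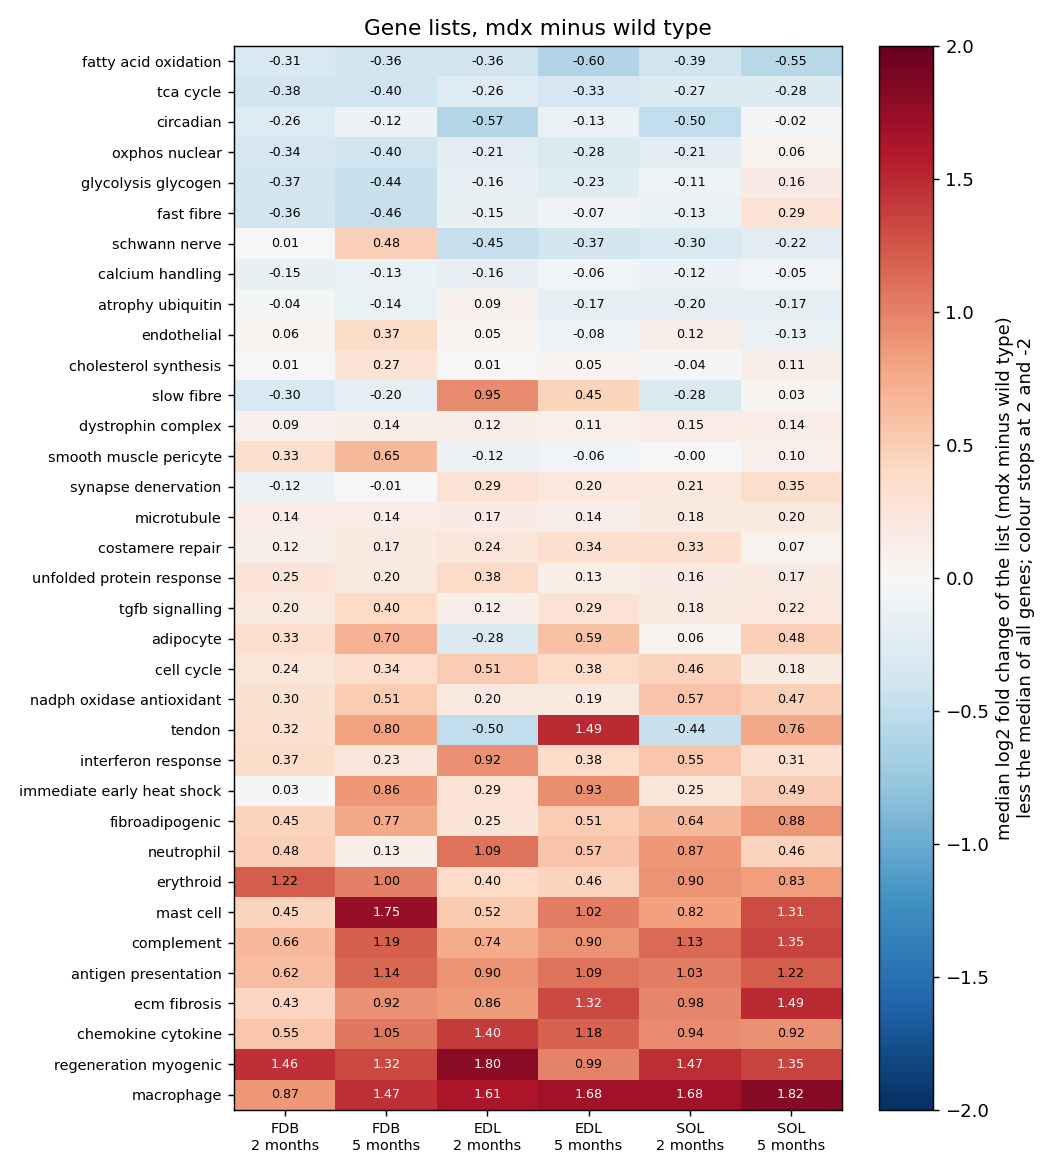
Median log2 change of each of the 35 tested gene lists in mdx minus wild type, less the median of all genes, by muscle and age, with colours that stop at −2 and 2. Macrophage, matrix and regeneration lists lay higher and fatty acid oxidation lower in all 6 comparisons, while the fast fibre list turned sign with quantile normalization in FDB.

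Genes of antigen presentation and macrophages were among the largest rises shared by every muscle at both ages. In all 6 comparisons 2169 genes were higher and 130 lower, against 85.4 and 0 if the 6 lists were independent, but 841 were higher and 815 lower with median-of-ratios scaling and 772 and 785 with quantile normalization. The 10 largest medians over the comparisons belonged to Ccl8 (2.94 log2), Mpeg1 (2.93), Ctss (2.87), H2-Aa (2.83), Tmem8c and Serpina3n (2.74 each), H2-Ab1 (2.73), Lgals3 (2.72), H2-Eb1 (2.66) and Cd74 (2.65). Each of them was higher in every mdx library than in the wild-type libraries of its muscle and age, although the Ccl8 rise in FDB at 2 months (1.13, adjusted p = 0.0238) was lost with median-of-ratios scaling. Among falls, Dusp26 had a median of −1.67, from −0.51 in FDB at 2 months to −3.12 in EDL at 5 months, Dmd −1.46 and Ppp1r1a −1.25. The other 7 of the 10 lowest, led by Gm14325 (−2.03) and Gm14326 (−1.77) and including Etohi1 (−1.44), lie in one region of chromosome 2.

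Among the largest falls with age in wild-type muscle was that of Col1a1. Col1a1, the main chain of type I collagen, fell in wild type from 317 ± 96.1 to 61.3 ± 5.63 RPKM in FDB, from 435 ± 83.0 to 27.0 ± 10.6 in EDL and from 152 ± 25.0 to 19.1 ± 10.6 in SOL between 2 and 5 months (n = 4 each), by 2.31, 4.04 and 3.13 log2. In wild-type EDL Dkk3, a Dickkopf-family gene, rose by 1.99, Pdk4, which limits glucose oxidation, by 1.88 and Actr3b by 1.74. In wild-type SOL Myh4 and the fast-fibre actinin Actn3 fell by 3.93 and 2.55, and by 5.30 and 3.31 without library ns31. Between ages 4213 genes passed in wild-type FDB (794 higher, 3419 lower), 2980 in EDL (322 and 2658) and 2165 in SOL (449 and 1716, with 1131 in all without library ns29). These splits turned with the scaling, from 18.8%, 10.8% and 20.7% higher as deposited to 53.9%, 53.5% and 49.6% with median-of-ratios scaling.

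In mdx muscle 738 genes changed with age in FDB (304 higher and 434 lower), 2205 in EDL (752 and 1453) and 5109 in SOL (2579 and 2530), where all 7 libraries at 5 months come from later ID blocks. Without one library the FDB count was 304 (ns01), 317 (ns04) or 459 (ns02) and the EDL count 1126 (ns35), 1148 (ns36) or 1369 (ns62). In FDB, EDL and SOL the counts were 2801, 1052 and 6664 without the third block, 1271, 3132 and 3204 without the second, 429, 962 and 2230 with only the compared groups, and 1565, 2898 and 5725 with ID blocks weighted equally. The share higher was 41.2%, 34.1% and 50.5% as deposited and 60.4%, 47.3% and 55% with median-of-ratios scaling. In mdx EDL Cdkn2a, which encodes senescence-associated cell cycle inhibitors, rose from 0.349 ± 0.102 (n = 4) to 3.49 ± 0.794 RPKM (n = 6), by 1.72 log2, and the nuclear receptor gene Nr4a1 rose by 1.47. The imprinted noncoding RNA Rian fell with age in all 3 mdx muscles, by 1.39, 1.52 and 2.1 log2 in FDB, EDL and SOL. A fall within mdx does not tell whether wild type fell too.

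The test of genotype by age asked whether the mdx effect itself differed between 2 and 5 months. In EDL Col1a1, among the largest differences, was at 299 ± 36.8 RPKM in mdx at 2 months (n = 4) and 150 ± 51.5 at 5 months (n = 6), so its effect rose by 2.98 log2 (adjusted p = 1.69e-06). Pdk4 went from 51.7 ± 5.1 to 198 ± 52.3 RPKM in wild type and from 112 ± 71.5 to 70.1 ± 41.8 in mdx (−2.53, adjusted p = 0.00199), and Actr3b from 0.910 to 5.33 RPKM in wild type and from 1.04 to 0.982 in mdx (−1.76, adjusted p = 7.22e-09). For Cfd (3.25), Chad (2.70), Fmod (2.62) and Angptl7 (2.61) the change in mdx went from −1.04, −1.05, −0.90 and −2.17 at 2 months to 2.22, 1.65, 1.72 and 0.44, so the fall of Angptl7 was no longer seen. Without the third-block libraries, which leaves 2 mdx libraries at 5 months, the differences were 2.35, 1.86, 2.06 and 1.99 and did not pass. Of 742 genes past the threshold in EDL 608 had a higher and 134 a lower effect, with 62 and 21 of at least 1 log2, and 434 and 461 passed without libraries ns47 and ns44 and 1230 with ID blocks weighted equally. The tendon list moved up between ages, with 8 of 11 members past the threshold (11 adjusted over the list alone), among them Comp at 2.58 and Cilp2 at 2.48. The tendon list had adjusted p = 3.03e-11, and adjusted p = 0.663 with an estimated correlation. Matrix genes moved up in 9 of 29 cases (16 adjusted over the list alone), with Col1a2 at 2.55. In wild-type library ns47 at 5 months Fmod was at 7.92 RPKM, with 43.9 to 58.2 in the other 3. Without it tendon genes moved up in 7 of 11 and matrix genes in 5 of 29 cases (9 and 11 adjusted over the lists alone, list adjusted p = 1.01e-09 and 1.01e-05), and the tendon median relative to all genes was 1.727, not 2.121. Circadian genes moved up in 8 of 16 cases (10 up and 2 down adjusted over the list alone), with Dbp at 1.61 and Per3 at 1.25. The matrix and circadian lists had adjusted p = 1.04e-06 and 0.025, and adjusted p = 0.962 for both with an estimated correlation.

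**Figure D5:**
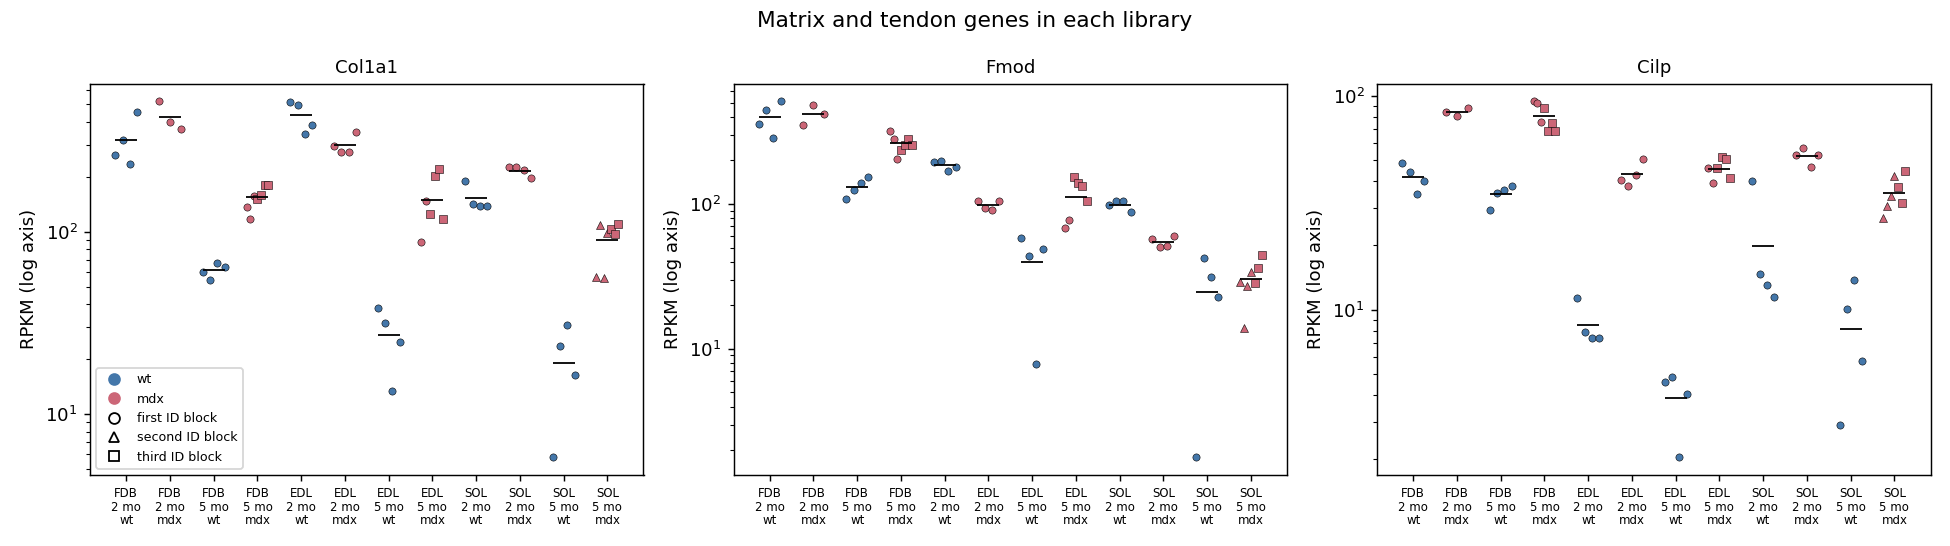
RPKM of Col1a1, Fmod and Cilp in each library on a log axis by muscle, age and genotype (blue wild type, red mdx; symbols mark the ID block), with a bar at each mean. Col1a1 in EDL fell with age from 435 to 27.0 RPKM in wild type and from 299 to 150 RPKM in mdx.

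Further lists had a lower mdx effect at 5 months in EDL. In fatty acid oxidation 2 of 22 genes moved down, with Cd36 at −0.75 (5 adjusted over the list alone), and in the interferon response, regeneration and cell cycle lists 0 of 16, 17 and 11 passed (0 adjusted over the lists alone). In the atrophy list 1 gene moved up and 1 down of 16, with Fbxo32 at −1.20, and in the slow fibre list 1 up and 2 down of 12, with Car3 at 1.38 and Tnnc1 at −1.26 (the same counts adjusted over the lists alone). Their adjusted p was 3.01e-08, 1.45e-05, 0.000722, 0.00962, 0.00969 and 0.0228, and adjusted p = 0.962 for each with an estimated correlation. In FDB 168 genes differed by age, 124 with a higher and 44 with a lower effect, and 4 and 5 of these by at least 1 log2. With each library left out the FDB count ran from 28 (without ns04) to 793 (without ns06), and array weights gave 5170 and ID blocks weighted equally 881. Clca4a, a chloride channel regulator gene, went from 0.166 ± 0.108 to 4.82 ± 1.35 RPKM in wild type and from 0.272 ± 0.11 to 1.15 ± 0.241 in mdx (−1.54, adjusted p = 8.8e-14). The FDB values of Rpph1 (1.86), Coch (1.61), Cldn5 (1.3), Cfb (1.06), Igfbp5 (0.98) and Mn1 (−1.01) each lost their call under at least one other setting. The FDB lists had few members past the threshold, complement 1 of 12 (9 adjusted over the list alone, Cfb), cholesterol synthesis 2 of 16 (8, with Msmo1 at 0.74 and Insig1 at 0.65) and matrix 1 of 29 (2, with Sparc at 0.76), all up. In antigen presentation, mast cell, Schwann cell, fibroadipogenic, macrophage and immediate early lists 0 members passed (7, 5, 0, 4, 0 and 1 adjusted over the lists alone), with tests up, and likewise 0 in the respiratory chain and atrophy lists (0 adjusted over the lists alone), with tests down. The adjusted p of these 11 lists ran from 0.000224 to 0.0379, and with an estimated correlation the smallest adjusted p was 0.962. Without the third-block libraries the Schwann cell median went from 0.46 relative to all genes to −0.16 and that of the respiratory chain from −0.10 to 0.08.

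In SOL 1756 genes differed by age, 1381 with a higher and 375 with a lower effect, and 54 and 13 by at least 1 log2. The count was 392 with only the compared groups in the model, 2779 with array weights, 2912 with ID blocks weighted equally and 4405 without the third-block libraries. Nr4a1 went from 26.3 ± 13.0 to 10.4 ± 1.95 RPKM in wild type and from 15.5 ± 2.67 to 50.5 ± 22.9 in mdx (2.70, adjusted p = 0.000255). Myh4 had a difference of 3.43 (adjusted p = 0.0184), which was 2.21 and did not pass without the third-block libraries, and Actn3 one of 2.04, also lost under other settings, as were Zbtb20 (−1.58) and Linc-md1 (−1.42). Respiratory chain genes moved up in 18 of 75 cases and 1 down (39 and 2 adjusted over the list alone), with Cox8b at 1.02, but the list's median of 0.28 relative to all genes turned to −0.09 without the second-block libraries. The respiratory chain list had adjusted p = 3.36e-06, and adjusted p = 0.962 with an estimated correlation. Matrix genes moved up in 12 of 29 cases (17 adjusted over the list alone), with Col1a1 at 1.82, and tendon genes in 4 of 11 (7 adjusted over the list alone), with Comp at 1.86. Fibroadipogenic markers moved up in 3 of 14 cases (5 adjusted over the list alone), with Gsn at 0.98. The matrix, tendon and fibroadipogenic lists had adjusted p = 2.36e-05, 0.00742 and 0.0139, and adjusted p = 0.962 for each with an estimated correlation. These rises lean on wild-type library ns29 at 5 months, with Fmod at 1.785 RPKM and 22.8 to 42.2 in the other 3. Without it 6, 2 and 2 members moved up (8, 2 and 2 adjusted over the lists alone), and the tendon and fibroadipogenic lists did not pass (adjusted p = 0.0036, 0.0957 and 0.106). Glycolysis genes moved up in 8 of 18 cases (12 up and 1 down adjusted over the list alone), with Pgam2 at 0.48 and a median of 0.21 that turned to −0.01 with quantile normalization. Endothelial genes moved down in 2 of 12 cases (2 adjusted over the list alone), with Flt1 at −0.70. The glycolysis and endothelial lists had adjusted p = 0.00674 for both, and adjusted p = 0.962 for both with an estimated correlation. The share of differences that were higher was 73.8% in FDB, 81.9% in EDL and 78.6% in SOL as deposited, and 44.7%, 44.6% and 54.1% with median-of-ratios scaling.

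The F test of genotype by muscle asked whether mdx effects differed between muscles. At 2 months 755 genes passed. Mybphl, a relative of myosin-binding protein H, rose in EDL from 0.230 to 5.75 ± 1.7 RPKM (n = 4), by 2.42 log2, with 0.05 in FDB and 0.01 in SOL (adjusted p = 2.2e-14).

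At 5 months 4655 genes passed the F test. Calml3, a calmodulin-like gene, rose in FDB from 1.04 ± 0.206 (n = 4) to 11.6 ± 3.33 RPKM (n = 7), by 2.59 (blocks 2.64 and 2.55), against 0.54 in EDL and 0.16 in SOL (adjusted p = 1.4e-18). Lrtm1 had changes of −0.28 in FDB, 0.44 in EDL and −2.40 in SOL (adjusted p = 2.4e-18), Dkk3 0.96, −2.73 and 0.53 (adjusted p = 2.7e-17) and Clca4a −1.41, −0.03 and 0.00 (adjusted p = 3.7e-16).

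The authors' deposited table gives q-values for 24446, 24442 and 20588 genes in FDB, EDL and SOL, where the model tested 12541, so the counts are not over the same genes. At a q-value of 0.05, for FDB the authors' deposited table has 6952 genes at 2 months (5969 higher and 983 lower) and 11559 at 5 months. For EDL it has 8859 and 11549, and for SOL 7294 and 11160. The genes past both thresholds numbered 4186 and 7774 in FDB, 6050 and 8448 in EDL and 4811 and 7993 in SOL. All had the same direction in both analyses.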

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

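Tests of transcript length in some genes, fast fibres, the Schwann cell pattern and a genetic difference on chromosome 2 were chosen after the result. So were splits after the additive effects were subtracted. The test of shared sequence replaced an earlier version once that was seen to decide nothing.

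In 7 of 99 groups of values 1 library stood far from the others, where chance gives about 1 in 20 groups, or 5. They were the depth of EDL wt library ns41 at 2 months (51.7 M reads, others at most 36.0), Utrn in EDL wt library ns44 at 2 months (4.02 RPKM, others at most 3.55) and Myh7 in EDL mdx library ns62 at 5 months (10.5, others at most 3.42). The other 4 concerned Myh4 at 5 months, in EDL wt ns47 (7800, others 9650 to 9910), FDB wt ns14 (203, others at most 136), SOL mdx ns58 (726, others at most 96.5) and SOL wt ns31 (427, others at most 21.3).

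The mdx effect differed between ages in 168 genes and 11 lists in FDB, 742 genes and 9 lists in EDL and 1756 genes and 6 lists in SOL. The smallest adjusted p of these lists was 0.962, 0.663 and 0.962 with an estimated correlation, and the FDB count ran from 28 to 793 with each library left out. Among named genes this held in FDB for Rpph1 (1.86 log2), Coch (1.61), Cldn5 (1.3), Cfb (1.06), Igfbp5 (0.98), Clca4a (−1.54), Ggta1 (−1.22) and Mn1 (−1.01). In EDL it held for Cfd (3.25), Col1a1 (2.98), Chad (2.70), Fmod (2.62), Angptl7 (2.61), Pdk4 (−2.53), Actr3b (−1.76), Angptl4 (−1.48), Cd24a (−1.43) and Dkk3 (−1.36). In SOL it held for Myh4 (3.43), Nr4a1 (2.70), Rn4.5s (2.19), Nnat (2.1), Actn3 (2.04), Apoo-ps (−2.34), Zbtb20 (−1.58) and Linc-md1 (−1.42).

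Between muscles the mdx effect differed in 755 genes at 2 months (669 for EDL and FDB, 195 for SOL and FDB, 295 for SOL and EDL) and in 4655 at 5 months (2308, 3227 and 2385). The smallest adjusted p of the F test at 2 months were 2.2e-14 for Mybphl, 5.2e-13 for Cyfip2, 1.3e-11 for Stom, 1.8e-11 for Prune2, 1.9e-11 for Mdfi, 5.4e-11 for Calml3, 3e-10 for Ttc9, 3.1e-10 for Itga4 and 8.4e-10 for Hoxd13. At 5 months they were 1.4e-18 for Calml3, 2.4e-18 for Lrtm1, 2.7e-17 for Dkk3, 3.7e-16 for Clca4a, 2.2e-15 for Itga4, 8e-15 for Hoxd13 and Nup133 and 2.5e-14 for Prune2 and Ttc9.

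In each mdx comparison the real split gave more genes than any other split tried of the same libraries, so chance is an unlikely source. The real count and the highest of the other splits were 4338 and 2337 in FDB, 6307 and 2757 in EDL and 5010 and 1513 in SOL at 2 months (35 splits each). At 5 months they were 7847 and 5540, 8621 and 7317, and 8055 and 6080 (100 splits each). Chance was also unlikely for age in wild type (4213 and 261, 2980 and 343, 2165 and 126 in FDB, EDL and SOL), in mdx EDL (2205 and 2084) and in mdx SOL (5109 and 4502). For age in mdx FDB 3 of 100 splits were as large (738 and 1599). Another split there gave more genes than the real one, so chance is not excluded. For genotype by age 10, 6 and 7 of 100 splits gave as many genes in FDB, EDL and SOL, so chance could not be excluded (168 and 5970, 742 and 5476, 1756 and 4539). For genotype by muscle it was 3 of 100 at 2 months (755 and 5249) and 7 of 100 at 5 months (4655 and 8217). Splits with several times the real count point to structure in the samples. With the additive effects subtracted, 2, 1 and 3 of 100 splits were as large for genotype by age (highest other 746, 551 and 2501). For genotype by muscle it was 1 each (137 and 2966). These shares make chance unlikely, although the highest split for genotype by age still lay above the real count in FDB and SOL. Structure in the samples may thus remain, and the ID block was not tested for it. For gene lists the real split gave the most calls of 100 (80), but others a median of 58 and up to 78. Without ns10 the real count was 76, so list calls at the preset correlation are weak evidence.

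The mdx SOL libraries at 5 months differed between the second and the third ID block in 5359 genes. Depth is argued against, since the difference had r = 0.008 across genes with that between shallow and deep EDL libraries. More fast fibres in the second block stay open, since that list went both ways, with 6 of 14 genes higher (Tnni2 at 1.02) and 5 lower (Myh4 at −2.86, or −1.74 without ns58). Transcript length may be part of it (Spearman rho = −0.356 across genes, against 0.158 and −0.069 for the FDB and EDL blocks). It is not the whole, since 5194 genes still differed with the length trend removed. Preparation or animals that differed by block were not tested.

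Schwann cell genes were higher in mdx FDB at 5 months in the third block only (median 0.883, first block −0.145). The block, not genotype alone, may be the source. The 4 abundant members differed between blocks by a median of 1.79 log2 (SD 0.435). Nerve tissue carried along in differing amounts is a candidate. All 12 endothelial and 7 erythroid genes were higher there too, so the shift was not particular to nerve. Third-block Mbp was 34.9 RPKM, first-block Mbp at 2 months 27.1 in wild type and 30.1 in mdx. A change of nerve with disease in third-block animals stays open.

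Of the 130 genes lower in all 6 comparisons 10 lay within 175061549 to 178023284 on chromosome 2, against at most 9 in 10000 random draws. Of the 15 genes measured there 3 others were lower without passing in each comparison, and Gm14327 (median −0.207, up to 0.075) and C330013J21Rik (0.227, up to 1.048) were not lower throughout, so the fall is not shared by every gene there. A genetic difference between mdx and wild-type mice here is a candidate. It cannot be told apart from a change in expression, since the SD between the 6 comparisons was 0.304 in these genes and 0.335 in 7 others. The genes share a median of 78.5% of 50-base words with other genes' transcripts, so reads shared between copies stay open too.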

How the results depend on the processing

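Settings without an ID block, with equal block weights or without the length trend were chosen after the data were seen. Of the counts of genes and lists, 116 stayed within 1.5 times the reported value under alternatives fixed beforehand and 35 did not, and 55 and 17 under those added. The cause was not tested where none is given. With a mean of at least 5 RPKM, which leaves 6431 genes to test, mdx minus wt gave 2015, 3229 and 2449 genes in FDB, EDL and SOL at 2 months and 3776, 4337 and 4335 at 5 months. Genotype by age gave 93 in FDB, genotype by muscle 437 and 2870 at 2 and 5 months, and age 2046, 1524 and 1342 in wild-type and 479, 1228 and 3166 in mdx FDB, EDL and SOL. Without a filter age gave 1111 in mdx FDB. With array weights mdx minus wt gave 7922 and 7700 in FDB and SOL at 2 months, genotype by age 5170, 2082 and 2779 in FDB, EDL and SOL, and genotype by muscle 3872 at 2 months. Age gave 6987, 5406 and 4385 in wild type and 4228 in mdx FDB with these weights. With only the compared groups in the model genotype by age gave 458 in FDB and 392 in SOL, genotype by muscle 1995 at 2 months, and age 4807 in wild-type EDL and 429, 962 and 2230 in mdx FDB, EDL and SOL. Without ns49 to ns53 genotype by age gave 540, 1406 and 1132 in FDB, EDL and SOL, genotype by muscle 1391 at 2 months, and age 1271 and 3204 in mdx FDB and SOL. Without ns54 to ns65 genotype by age gave 280 in EDL and 4405 in SOL, genotype by muscle 1451 at 2 months, and age 2801 and 1052 in mdx FDB and EDL. With ID blocks weighted equally genotype by age gave 881, 1230 and 2912, genotype by muscle 1537 at 2 months, and age 1565 in mdx FDB. With the length trend removed genotype by age gave 263 in FDB. Of 210 list tests 80 passed camera, 0 with an estimated correlation (smallest adjusted p 0.259) and 151 with fry, which tests each list against no change and not against other genes. No paired analysis was possible because the data columns carry no replicate numbers. No gene symbol is repeated, so keeping the highest row per symbol was not run, and robust eBayes does not apply to list tests. Depth, 20.3 M reads in the shallowest library, limits what genes near 0.5 RPKM can show.

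With each library left out in turn mdx minus wt gave 2616 to 4073, 5363 to 6297 and 4242 to 4964 genes in FDB, EDL and SOL at 2 months and 7219 to 8100, 8044 to 8664 and 7422 to 8160 at 5 months. Genotype by age gave 28 to 793, 434 to 947 and 1286 to 2396, genotype by muscle 533 to 817 and 3998 to 5371, and lists 76 to 85. Among lists of genotype by age, some single library took the call from atrophy, fibroadipogenic, immediate early, macrophage and respiratory chain in FDB, atrophy, cell cycle, circadian and slow fibre in EDL, and fibroadipogenic and tendon in SOL. Age gave 3239 to 3965, 2041 to 2930 and 1131 to 2150 in wild type and 304 to 782, 1126 to 2743 and 4188 to 5543 in mdx. Moves of over 1.5 times came for genotype by age in FDB without ns01 (265), ns02 (38), ns04 (28), ns06 (793), ns08 (319), ns09 (92), ns10 (70), ns11 (292), ns12 (68), ns13 (64), ns14 (58), ns54 (105), ns55 (87), ns56 (107) or ns57 (100), and in EDL without ns44 (461) or ns47 (434). They also came for FDB at 2 months without ns01 (2616) and for age in mdx EDL without ns35 (1126), ns36 (1148) or ns62 (1369), in mdx FDB without ns01 (304), ns02 (459) or ns04 (317) and in wild-type SOL without ns29 (1131).

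Of 589 calls of named genes 100 were lost under some alternative fixed beforehand, 88 with a library left out and 64 under those added. Signs turned with median-of-ratios scaling, quantile normalization and the length trend removed for Nup133 (−0.097, −0.166, −0.10) and Prune2 (−0.229, −0.203, −0.202) in FDB at 5 months, with the first for Ttc9 there (−0.243) and for Ndufa13 (−0.008) and Nup133 (−0.010) in EDL at 5 months. They turned with quantile normalization for Nup133 (−0.065) and Utrn (−0.239) in EDL, 0610040J01Rik in FDB (−0.006, and −0.046 with the length trend removed) and Aldoa in genotype by age of SOL (−0.039). Removing the length trend turned Hoxd13 in SOL (−0.145 and −0.151 at 2 and 5 months). Leaving out ns49 to ns53 turned Apoo-ps in genotype by age of SOL (0.038) and Snhg9 (−0.096) with age in mdx SOL. Leaving out ns54 to ns65 turned Mir6240 (−0.193) and Mrgpra6 (−0.006) in FDB at 5 months and Mrgpra6 (−0.031) with age in mdx SOL.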

Other observations

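Several gene lists moved without passing camera. All 6 mast cell genes rose in FDB, EDL and SOL at 5 months (6 each adjusted over the list alone), with the proteases Mcpt4 at 2.30, 1.42 and 2.08 and Tpsb2 at 2.08, 1.38 and 2.02, and 0, 2 and 4 rose at 2 months (list adjusted p = 0.0524, 0.424 and 0.183 at 5 months). Their median relative to all genes was 1.034 and 2.245 in the first and the third block of FDB, 1.341 and 0.860 in EDL, and 1.785 and 0.673 in the second and the third block of SOL. Of 15 immediate early and heat shock genes 10, 12 and 9 rose at 5 months in FDB, EDL and SOL, with Fos at 2.45, 2.75 and 2.69 and Junb at 1.78, 2.93 and 2.38, and their block medians were 0.762 and 0.855, 0.687 and 1.017, and 0.786 and 0.206. Adipocyte genes rose in 8, 7 and 7 of 10 cases at 5 months and 1 fell in SOL, with adiponectin, Adipoq, at 2.05, 1.19 and 1.55. In EDL their median relative to all genes was −0.040 in the first block and 0.704 in the third. In FDB at 5 months 7 of 10 smooth muscle and pericyte genes rose and 1 fell, with Acta2 at 2.02, Cnn1 at 1.75 and Myh11 at 1.46, and the median was −0.104 in the first block and 0.754 in the third. With median-of-ratios scaling 5, 6 and 6 mast cell, 8, 10 and 8 immediate early, 6, 6 and 6 adipocyte and 7 FDB smooth muscle genes rose at 5 months.

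Of 16 genes of the dystrophin complex 6 to 12 rose and 1 or 2 fell in each comparison as deposited, but 1 to 6 rose and 1 to 5 fell with median-of-ratios scaling (list median 0.088 to 0.148 relative to all genes), with the caveolin Cav3 higher in all 6 (0.36 to 0.94). Nos1, the neuronal nitric oxide synthase bound to the complex, fell in SOL by 1.0 and 1.08 at 2 and 5 months, in EDL by 0.54 and 0.77 and in FDB at 5 months by 0.63, with 0.02 in FDB at 2 months. Microtubule genes rose in 11 to 14 of 21 cases and fell in 0 to 3 (6 to 10 and 1 to 7 with that scaling), with Tubb2b at 1.04 to 2.16 and Tuba1b at 0.77 to 1.46. NADPH oxidase and antioxidant genes rose in 10 to 14 of 20 cases and fell in 1 to 5 (7 to 11 and 2 to 8), with the oxidase subunit Cybb at 1.11 to 1.72.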
